A study of Mus musculus with 8 samples.

How the data were processed

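RNA was measured in 8 organoid cultures of mouse embryonic hindstomach epithelium, 4 with the genotype Shh-Cre (Ctrl) and 4 with Shh-Cre;YAP5SA. Per the labels' protocols, total RNA was extracted with an RNeasy Plus Universal Mini kit (Qiagen), a VAHTS Universal V8 kit was used for the libraries, and both ends of the fragments were sequenced on an Illumina NovaSeq. The authors deposited raw counts, whole numbers of reads per gene and library that were not normalized. Per the submitters' processing notes, cutadapt, HISAT2 2.0.1 and HTSeq 0.6.1 were used and the genome build was mm9. The annotation, the strand setting and any filter are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be assigned with certainty. Genes with near-identical copies, such as those of ribosomal proteins, Gapdh, Eef1a1, Xlr3a and the mitochondrial genes, are uncertain for the same kind of reason.

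The table has 56691 rows, of which 26206 had at least 1 count. Gene symbols were used as the file gives them. Of 53170 rows with a symbol, 50664 matched a symbol in GENCODE M21 (GRCm38). Of 3521 rows with an Ensembl identifier only 102 matched a gene identifier there, and these 3521 rows hold 0.0931% of all counts. As the build of the file's annotation could not be settled, no coordinates are given. GENCODE M21 transcript lengths, on GRCm38, served only for a check of length bias.

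Groups and replicate numbers were taken from the sample titles. No label names a batch that differs between libraries. Replicates of a group were compared before use: the chi-square per degree of freedom between their counts was 4.94 to 38.3, so no pair agreed within sampling noise. Correlations of log2 CPM were 0.982 to 0.990 within Ctrl, 0.985 to 0.991 within YAP5SA and 0.875 to 0.899 between the groups.

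Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 13812. Libraries were scaled by the TMM method, with factors of 0.92 to 0.97 in Ctrl and 1.04 to 1.08 in YAP5SA. The quasi-likelihood F test compared the 2 groups with no covariate, two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with 0.05 as the threshold. Standard errors of log2 fold changes are the log2 fold change divided by the square root of F. The common biological coefficient of variation was 0.127. Means and SDs are of CPM over 4 libraries with TMM scaling. Where a group had 0 counts, fold bounds use a floor of 3 counts over the group, and with 1 to 3 counts the ratio of counts per total has an exact 95% interval. Floors and intervals cover counting error only, since the reads carry no molecular identifiers.

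Gene lists, 43 in number, were fixed from general knowledge before the data were examined, and comprise gastric lineages, other cell types, pathways and signs of RNA quality. Lists with at least 5 tested members, 37 of them, were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, adjusted over the lists, then with an estimated correlation and with fry. Of the list genes, 240 were not tested, of which 83 had 0 counts in all libraries.

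The genes named were chosen by a rule written before the data were examined. It takes the 12 highest and 12 lowest log2 fold changes among called genes that separate the groups completely and have a mean log2 CPM of at least 2, leaving out predicted genes and pseudogenes. It adds up to 4 tested members of each list with the smallest p, 35 genes of the stomach and of YAP signalling fixed in advance, and the 5 most counted genes of each group. Some genes this rule takes are not reported here. Other list members named as exceptions or further examples were chosen after their values were seen.

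The procedure was tested on simulated data for the same comparison with 200 genes changed and 13601 genes tested. It recovered 60.9% of 64 genes changed 1.5-fold, 82.1% of 67 changed 2-fold and all 65 changed 4-fold. Of its calls 9.14% were false, a share above the threshold for adjusted p-values. In the real data 8907 of 13812 genes were called, far more than were changed in the simulation. The simulation thus did not test scaling with so many changes, and its shares need not hold for the real calls. At the total counts of 17387372 to 25841256 per library a floor of 3 counts, taken for 0 counts in a library, corresponds to 0.116 to 0.173 CPM.

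The alternatives were DESeq2 1.42.0, limma-voom, RLE, upper quartile and library size scaling, no filter on low counts, a filter at 1 CPM in 4 libraries, the replicate number as a block, 1 surrogate variable from sva 3.50.0, leaving out the genes above 1% of a library, a minimum effect of 1 on the log2 scale and leaving out each library in turn. Leaving out the sex-linked genes was added after the data were seen. All 35 divisions of the 8 libraries into 4 and 4 were also run.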

Results

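Bulk RNA sequencing was done on organoids, 3-dimensional cultures of epithelium from the mouse hindstomach, the glandular part of the stomach, taken at embryonic day 18.5. The cultures had spent 5 days in growth medium and 7 further days in differentiation medium. Of the 8 libraries, 4 came from Shh-Cre cultures (Ctrl) and 4 from Shh-Cre;YAP5SA cultures (YAP5SA). YAP5SA is an active form of the Hippo pathway coactivator YAP whose inhibitory phosphorylation sites are mutated. Total counts were 18225648, 18379170, 25841256 and 19006061 in Ctrl replicates 1 to 4 and 20479760, 18316512, 17387372 and 21039926 in YAP5SA replicates 1 to 4. The labels give the replicates as separate samples without naming embryos, litters or culture days, so the p-values measure only the spread between these samples.

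The groups differed in sex-linked transcripts as completely as in genotype. Xist, the RNA that coats the inactive X chromosome in female cells, had 8436 to 12237 counts in the Ctrl libraries and 0 to 8 in the YAP5SA libraries. The Y-linked genes Kdm5d, Uty, Ddx3y and Eif2s3y had 0 counts in every Ctrl library and between 880 and 3854 in every YAP5SA library. Y-linked counts were thus present in 0 of 4 Ctrl and 4 of 4 YAP5SA libraries. Among genes known to escape X inactivation, Kdm6a fell by 0.95, Kdm5c fell by 0.85 and Ddx3x fell by 0.41 on the log2 scale, while Eif2s3x was at 0.18 (edgeR adjusted p = 0.102). Eif2s3x was at 0.24 and called without Ctrl replicate 1 (adjusted p = 0.0233) or without YAP5SA replicate 3 (adjusted p = 0.0430). Every difference below is therefore one of genotype and of these sex-linked transcripts at once, and no library separates them. The labels do not say whether the cultures of a group share an embryo or a preparation. If they do, that source is confounded with genotype as well, and the replicates do not measure the spread between animals.

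**Figure D1:**
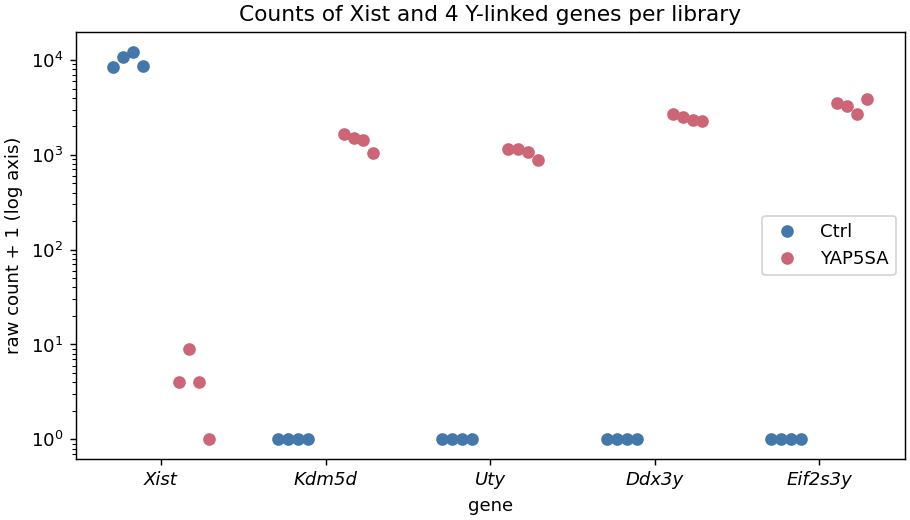
Raw counts plus 1 (log axis) of Xist and of the Y-linked genes Kdm5d, Uty, Ddx3y and Eif2s3y, with each point 1 library (4 Ctrl, 4 YAP5SA). Ctrl libraries hold 8436 to 12237 Xist counts and 0 Y-linked counts, and YAP5SA libraries hold 0 to 8 Xist counts and 880 to 3854 counts of each Y-linked gene.

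The comparison asks how active YAP changes the transcriptome of hindstomach epithelium under differentiation conditions. By the camera test, lists of YAP/TEAD targets, ribosomal protein genes and cell cycle genes were higher in YAP5SA, and lists of surface mucous cell markers, gland mucous cell markers and gastric transcription factors were lower. With an estimated correlation only the YAP/TEAD list of these kept its call (adjusted p = 0.0492), against adjusted p = 0.65 for the ribosomal and cell cycle lists and adjusted p = 0.41 for the 3 lower lists. That setting also takes its degrees of freedom from the libraries rather than the genes, so these losses are not due to correlation alone. Fry, which does not compare a list with other genes, called all of these lists (adjusted p at most 0.00282). It also called 30 of the 37 lists tested. Endogenous and transgenic transcripts could not be told apart in the row for Yap1, because the labels give neither the species of the transgene nor how its reads were counted. Yap1 was at 118 ± 11 CPM in Ctrl and 140 ± 2.22 CPM in YAP5SA (SD, n = 4 each), a log2 fold change of 0.25 (SE 0.08, edgeR adjusted p = 0.0111). Without Ctrl replicate 3 the Yap1 value was 0.19 and no longer called (adjusted p = 0.0711). Its paralogue Wwtr1, which encodes TAZ, rose by 0.90 (SE 0.09) on the log2 scale.

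Of 13812 genes tested, 8907 (64.5%) differed between the groups at an edgeR adjusted p under 0.05, 4577 higher and 4330 lower in YAP5SA. Scaling by library size alone called 5742 higher and 3201 lower, with the median of all genes shifted to a log2 fold change of 0.19 from 0.02. More than 2-fold changes were found for 1937 higher and 1589 lower genes, and more than 8-fold changes for 396 and 252. The 4 libraries of one group all lay above the 4 of the other for 58.7% of tested genes, where chance gives 2.86%. In a principal component analysis of log2 CPM the first component held 84.5% of the variance and separated the groups, and the second held 4.62%.

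**Figure D2:**
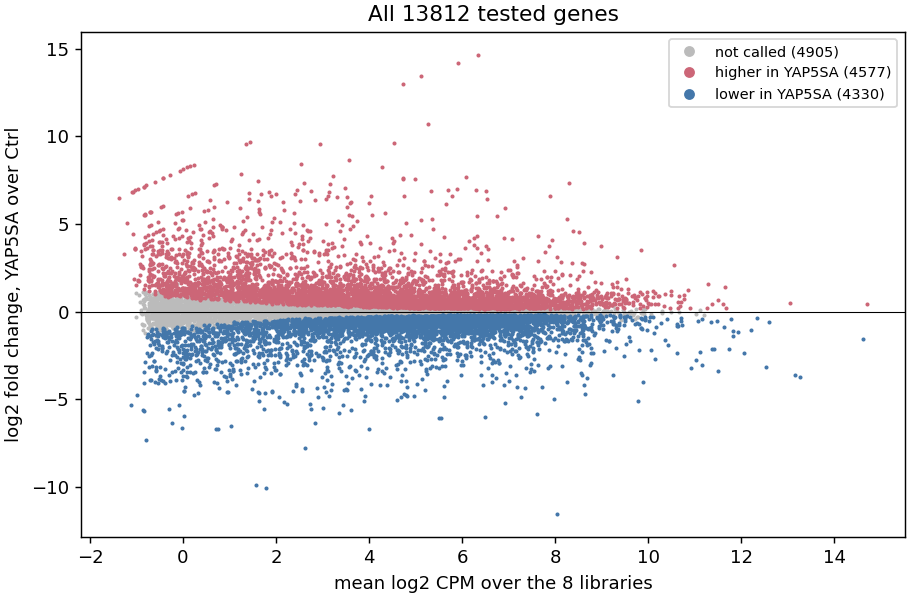
Log2 fold change (YAP5SA over Ctrl) against mean log2 CPM for the 13812 tested genes, each point 1 gene, coloured by edgeR call at an adjusted p of 0.05. The 4577 higher and 4330 lower genes span the whole range of expression, and the extreme points include the Y-linked genes at the top and Xist at the bottom.

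Among separated genes with a mean log2 CPM of at least 2, predicted genes and pseudogenes left out, the steepest rises after the Y-linked genes were in transcripts nearly missing from Ctrl. Dlc1 had 3 Ctrl counts against 6261 in YAP5SA, a ratio of 2201 (95% counting interval 753 to 10677). Siglecg, a sialic acid-binding lectin, had 1 against 1220 counts (ratio 1287, interval 231 to 50867), and the serine protease Prss52 had 2 against 915 (ratio 483, interval 133 to 3991). On the log2 scale Dlc1 was at 10.71 and Siglecg at 9.59, against 13.57 without Ctrl replicate 4 and 11.22 without Ctrl replicate 1, the libraries that hold all their Ctrl counts. Log2 fold changes were 9.62 (SE 0.35) for the growth factor carrier Igfbp2, 8.64 (SE 0.30) for the glypican Gpc3 and 8.28 (SE 0.30) for the myelin protein gene Pmp22. The kinase subunit gene Camk2b rose by 7.76 (SE 0.37) and the potassium channel subunit gene Kcnab1 by 7.68 (SE 0.22). For the Y-linked genes, with 0 Ctrl counts, the floor of 3 counts over the group gives at least 4649-fold higher Eif2s3y, 3451-fold Ddx3y, 1981-fold Kdm5d and 1495-fold Uty.

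By the same rule, the steepest fall after Xist (log2 fold change -11.53, SE 0.25) was that of Capn9, a calpain of gastric mucous cells, at -7.79 (SE 0.36). Next came Efcab1 at -6.68 (SE 0.27), the X-linked Xlr3a at -6.33 (SE 0.29), and Agr2, a disulfide isomerase needed for mucin production, at -6.06 (SE 0.25). Gsdma2 was at -6.04, Ptprn2 at -6.03, the sulfotransferase Sult1d1 at -5.81, Sectm1b at -5.59, Elapor1 at -5.50, Tm4sf5 at -5.34 and the lipase gene Mgll at -5.26. Single libraries carry much of the residual signal in the near-empty group. Without Ctrl replicate 1 Igfbp2 was at 10.93, without Ctrl replicate 4 Camk2b was at 9.60 on the log2 scale, without YAP5SA replicate 1 Capn9 was at -9.04, without YAP5SA replicate 2 Xist was at -12.33, and without YAP5SA replicate 4 Efcab1 was at -7.53.

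Fixed lists of genes were compared next, 43 in all, of which 37 had at least 5 tested members. Camera called 9 of the 37, 4 of them higher and 5 lower, and 1 with an estimated correlation, the YAP/TEAD targets. Of the other divisions of the 8 libraries into 4 and 4, the 16 that keep 3 libraries of a group together called 5 to 12 lists and the 18 with 2 of each group called 0 to 5. The counts of called members were the same adjusted over the list alone as over all genes tested for 38 of the 42 lists with a tested member. The 4 exceptions are given beside their lists.

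YAP/TEAD target genes rose as a group. Of 24 tested, 19 were higher, 2 lower and 3 not called, adjusted over the list alone as well, with a median log2 fold change of 1.34 (camera adjusted p = 4.53e-06, and adjusted p = 0.0492 with an estimated correlation). Ccn1, a matricellular protein gene, went from 32.0 ± 3.29 to 433 ± 33.2 CPM (log2 fold change 3.76, SE 0.09). Tgfb2, a TGF-beta ligand, went from 0.270 ± 0.177 to 52.2 ± 2.20 CPM (7.60, SE 0.19). Amotl2, a feedback regulator of YAP, rose by 2.33 (SE 0.07), the receptor kinase gene Axl by 3.57 (SE 0.15), Ankrd1 by 2.10 (SE 0.15) and Ccn2 by 1.88 (SE 0.13). Dock5 fell by 0.41 and Nt5e fell by 0.32 on the log2 scale, and the Nt5e call ended without Ctrl replicate 2 (-0.30, adjusted p = 0.0504) or YAP5SA replicate 1 (-0.28, adjusted p = 0.0714).

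Among 28 Hippo pathway components, 15 were higher, 6 lower and 7 not called (camera adjusted p = 0.0593, 0.0492 without YAP5SA replicate 1 and 0.0362 without YAP5SA replicate 2). Frmd6 rose by 2.78 (SE 0.09), the YAP partner Tead1 by 2.32 (SE 0.11) and the YAP kinase Lats2 by 1.79 (SE 0.09). Mob1b fell by 1.15 and Nf2 fell by 0.68 on the log2 scale. Vgll1, a TEAD cofactor, had 0 counts in every Ctrl library and 33 to 46 in the YAP5SA libraries, and is named after its values were seen.

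**Figure D3:**
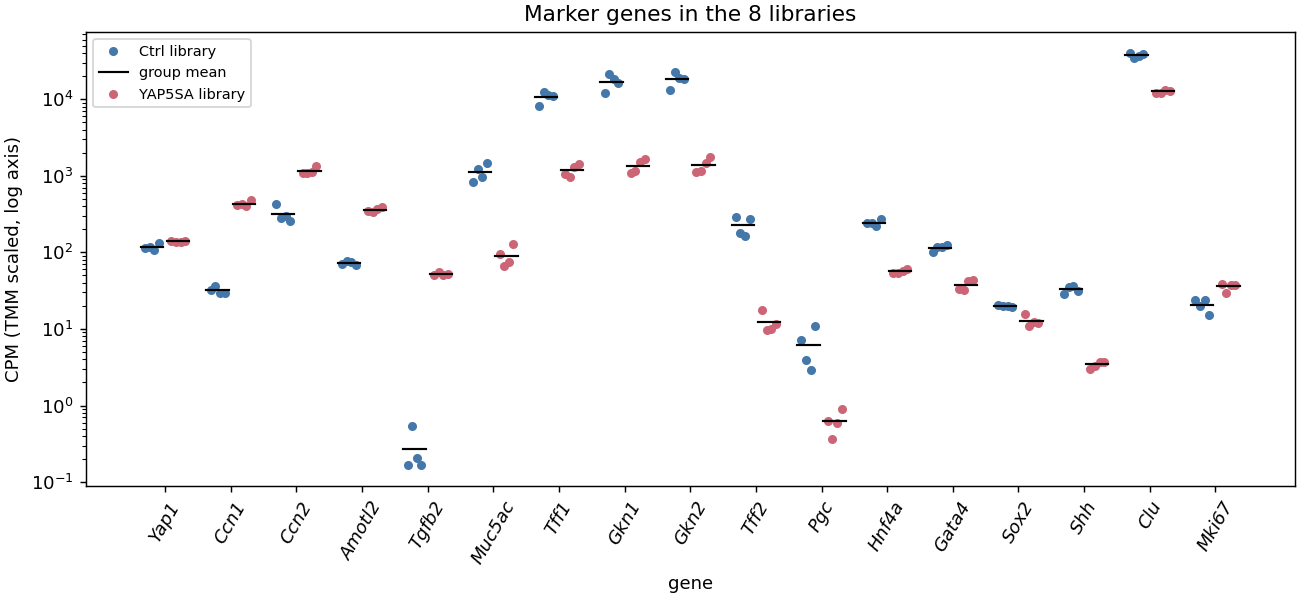
CPM with TMM scaling (log axis) of 17 genes, each point 1 library (4 Ctrl, 4 YAP5SA) and each bar the group mean. Ccn1, Ccn2, Amotl2 and Tgfb2 lie higher in all YAP5SA libraries, and Muc5ac, Tff1, Gkn1, Gkn2, Tff2, Hnf4a, Gata4, Shh and Clu lie lower in all of them.

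Surface mucous (pit) cell markers fell together. All 19 tested were called, 18 lower and 1 higher, also when adjusted over the list alone, with a median of -3.02 (camera adjusted p = 4.85e-09, and adjusted p = 0.41 with an estimated correlation). The mucin gene Muc5ac went from 1122 ± 286 to 90.7 ± 27.5 CPM (-3.63, SE 0.22). The secreted gastric peptide genes Gkn2, Gkn1 and Tff1 were at -3.74 (SE 0.18), -3.64 (SE 0.18) and -3.17 (SE 0.15). They made up 1.71%, 1.59% and 1.01% of all counts in Ctrl and 0.145%, 0.144% and 0.127% in YAP5SA. Mucl3 fell by 3.38, Vsig1 fell by 3.06, Anxa10 fell by 3.02 and Sult1c2 fell by 2.67 on the log2 scale. The exception was Tmem171, which rose by 1.12.

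Mucous neck and antral gland mucous cell markers were lower as well, 10 of 13 tested, with 3 higher and a median of -2.48 (camera adjusted p = 0.0175, and adjusted p = 0.41 with an estimated correlation). Tff2, a trefoil peptide of gland mucous cells, fell from 226 ± 62.8 to 12.2 ± 3.83 CPM (-4.20, SE 0.23). Galnt6, a mucin glycosyltransferase, was at -4.21 (SE 0.15), the secretory cell transcription factor Spdef at -3.68 (SE 0.19) and Gkn3 at -3.72. In the other direction went Wfdc2 (1.42, SE 0.07), the water channel gene Aqp5 (0.85, SE 0.23) and Lyz2, with 3 against 71 counts (ratio 25.0, 95% counting interval 8.20 to 124; log2 fold change 4.26, and 5.21 without Ctrl replicate 1). The gland mucin gene Muc6 had 17 counts over the Ctrl libraries and 6 over the YAP5SA libraries and was not tested.

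Foregut and stomach transcription factors were lower in 17 of 26 tested genes, higher in 5 and not called in 4, with a median of -0.65 (camera adjusted p = 0.000846, and adjusted p = 0.41 with an estimated correlation). Hnf4a, a regulator of glandular epithelial genes, fell from 242 ± 20.1 to 56.6 ± 3.11 CPM (-2.10, SE 0.08). Gata5 was at -3.22 (SE 0.13), Foxa3 at -3.08 (SE 0.14), Klf4 at -2.97 (SE 0.14) and Gata4 at -1.59 (SE 0.11). Sox2, a foregut progenitor factor, fell by 0.65 (SE 0.12). The antral factor Pdx1, at 1.60 ± 0.549 CPM in Ctrl and 2.75 ± 0.780 in YAP5SA, was at 0.76 (SE 0.30, adjusted p = 0.0379). Its call ended without Ctrl replicate 1 (adjusted p = 0.0782), 2 (0.0781) or 4 (0.112) and without YAP5SA replicate 1 (0.138), 3 (0.0687) or 4 (0.0632). The morphogen gene Shh, in no list, fell from 32.8 ± 3.37 to 3.44 ± 0.315 CPM (-3.26, SE 0.12).

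Markers of other gastric lineages went in both directions. For chief cells, 4 of 8 tested genes were lower and 3 higher (camera adjusted p = 0.556), with the neonatal protease gene Cym at -5.10 (SE 0.30), the pepsinogen gene Pgc at -3.29 (SE 0.43) and Nrn1 at 1.73 (SE 0.23). Parietal cell markers were lower in 7 of 12, higher in 1 and not called in 4, with a median of -0.81 (camera adjusted p = 0.0944). Among them the carbonic anhydrase gene Car2 fell by 2.33, Clic6 fell by 2.31 and Sstr2 fell by 3.31 on the log2 scale. Car2 was at 2641 CPM and Clic6 at 151 CPM in Ctrl, far above Atp4a, so their falls need not mark parietal cells. The proton pump subunit gene Atp4a was at 3.05 ± 1.46 and 4.46 ± 0.875 CPM (0.55, adjusted p = 0.113), but at 0.87 (adjusted p = 0.00894) without Ctrl replicate 1. Tuft cell markers went both ways in 7 tested, 4 higher and 3 lower (camera adjusted p = 0.624), with Dclk1 at 4.98 (SE 0.24), Ptgs1 at 3.49 (SE 0.16) and Avil at -4.17 (SE 0.16). Only 4 enteroendocrine markers were tested, and Tph1 (6.95, SE 0.37) and Slc18a2 (0.95) were higher while Ddc (-3.57, SE 0.34) and Slc18a1 (-1.25) were lower, so that the median was -0.15 and the mean 0.77.

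Several lineage genes lay under the test's count filter. Totals over the Ctrl and YAP5SA libraries were 46 and 5 for Cblif, 13 and 1 for Atp4b (12.3-fold lower, 95% counting interval 1.85 to 524), 15 and 6 for Chga, and 31 and 8 for Ghrl. Gast and Sst had 0 counts in all libraries, where a floor of 3 counts per library corresponds to 0.116 to 0.173 CPM. The basal keratin gene Krt5 had 124 and 4 counts, Trp63 had 1 and 0, and Cdx2 had 6 and 3.

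Stem and progenitor markers were higher in 9 of 15 tested genes, lower in 4 and not called in 2 (camera adjusted p = 0.273). Cd44 rose by 2.12 (SE 0.10), Lrig1 by 1.58 (SE 0.10) and Lgr5 by 2.27 (SE 0.41), the last from 0.289 ± 0.177 to 1.38 ± 0.198 CPM. Prom1 fell by 1.67 and Bmi1 fell by 1.15 on the log2 scale. Fetal and regenerative epithelial genes moved in both directions, with 14 higher, 14 lower and 5 not called of 33 (camera adjusted p = 0.975). Their median of 0.11 and mean of -0.01 differ in sign, and the median was -0.04 when the libraries were scaled on the reference genes. Anxa1 rose by 2.64 (SE 0.18), while Il33 was at -3.23 (SE 0.15). Clu, a marker of regenerating epithelium and the most counted gene in Ctrl, was at -1.58 (SE 0.08), with 3.52% of Ctrl and 1.34% of YAP5SA counts. Ly6a, which encodes SCA-1, was at 0.14 (adjusted p = 0.242), and at 0.25 (adjusted p = 0.00388) without Ctrl replicate 1.

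Metaplasia (SPEM) genes were lower in 10 of 17, higher in 6 and not called in 1 (camera adjusted p = 0.457), with the iron-binding lipocalin gene Lcn2 at 7.55 (SE 0.24) and Tff2 at -4.20. Squamous and basal epithelial markers were higher in 4 of 15 tested and lower in 6, or 7 when adjusted over the list alone (camera adjusted p = 0.498). The cornified envelope gene Sprr3 rose by 6.59 (SE 0.24) and Krt4 by 3.04 (SE 0.17), while Ivl, another envelope gene, was at -3.09 (SE 0.15). Intestinal epithelial markers were lower in 7 of 11 and higher in 2 (camera adjusted p = 0.11). Lgals4 was at -4.69 (SE 0.15), the microvillus gene Vil1 at -2.55 (SE 0.17) and Fcgbp at 6.16 (SE 0.31).

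Cell cycle genes were mostly higher, 28 of 40, with 2 lower and 10 not called and a median of 0.92 (camera adjusted p = 0.000634, and adjusted p = 0.65 with an estimated correlation). E2f1, a driver of S phase entry, rose by 2.10 (SE 0.12), the ribonucleotide reductase subunit gene Rrm1 by 1.77 (SE 0.12) and the proliferation marker Mki67 by 0.80 (SE 0.14), from 20.6 ± 4.16 to 35.9 ± 4.08 CPM. The mitotic kinase gene Plk1 was at -2.27 (SE 0.15). Cytosolic ribosomal protein genes were higher in 37 of 40, lower in 0 and not called in 3, with a median of 0.77 (camera adjusted p = 4.85e-09, and adjusted p = 0.65 with an estimated correlation). Rpl22 rose by 1.31 (SE 0.09), Rpl5 by 1.12 (SE 0.09) and Rps19 by 1.12 (SE 0.10). Their values are uncertain where reads could be shared with pseudogenes.

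Signalling genes gave no further call by camera. Wnt targets were higher in 8 of 14, lower in 0 and not called in 6 (adjusted p = 0.0962). Notch pathway genes were lower in 7 of 13 and higher in 2 (adjusted p = 0.138), with Dll4 at -3.55 (SE 0.32), Dtx4 at -2.41 (SE 0.12) and Hes1 at -0.78 (SE 0.09). BMP and TGF-beta pathway genes were higher in 12 of 20 and lower in 7 (adjusted p = 0.0962), and beside Tgfb2 the ligand genes Bmp4 (3.25), Bmp7 (2.94, SE 0.15) and Inhba (2.60, SE 0.19) rose. EGFR ligand and receptor genes were higher in 8 of 18 and lower in 6 (adjusted p = 0.861), with Btc at -1.99, Areg at -1.54 and Hbegf at 1.16, and a positive median where fry's direction was down. AP-1 and immediate early genes were higher in 6 and lower in 6 of 19 (adjusted p = 0.851), with Dusp1 at 3.35 (SE 0.16) and Btg2 at -1.01, and their median of -0.08 was 0.10 with library size scaling while fry's direction was up.

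Cell adhesion, hemidesmosome and basement membrane genes were higher in 16 of 28 tested, or 17 when adjusted over the list alone, and lower in 8 (camera adjusted p = 0.0577). That p was 0.0369 without Ctrl replicate 2, 0.0492 without YAP5SA replicate 1 and 0.0386 without YAP5SA replicate 4. The collagen IV genes Col4a1 and Col4a2 rose by 4.08 (SE 0.09) and 4.54 (SE 0.13), from 27.3 ± 3.07 to 462 ± 13.7 CPM and from 30.3 ± 6.15 to 705 ± 38.4 CPM. Thbs1 rose by 3.53 (SE 0.09) and the tenascin gene Tnc by 4.93 (SE 0.22). Actin cytoskeleton genes were higher in 12 and lower in 9 of 25 (adjusted p = 0.457), with a median of 0.07 that was -0.08 under reference gene scaling and -0.03 without Ctrl replicate 1. Caldesmon (Cald1) rose by 5.31 (SE 0.13), while Tagln2 was at -1.87 (SE 0.08). Tight and adherens junction genes were lower in 15 and higher in 7 of 25 (adjusted p = 0.115), with Cldn18 at -2.32, Dsc2 at -2.24 and Cldn3 at 4.03 (SE 0.17).

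Of 14 tested genes of epithelial-mesenchymal transition, 6 were higher and 6 lower, with a median of -0.52, a mean of 0.70 and a camera test on the higher side (adjusted p = 0.975). The membrane protease gene Mmp14 rose by 5.48 (SE 0.11), and the intermediate filament gene Vim from 0.739 ± 0.572 to 25.6 ± 2.11 CPM (5.15, SE 0.31). The epithelial adhesion gene Epcam also rose, from 296 ± 26.4 to 592 ± 24.0 CPM, and Cdh1 fell by 0.78 on the log2 scale. In the same libraries the mesothelial gene Upk3b, chosen after its values were seen, rose by 2.11 (SE 0.25).

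Markers of cell types other than stomach epithelium were sparse. Of 20 fibroblast and mesenchyme markers only Mfap5 was tested, with 2 against 57 counts (ratio 30.1, 95% counting interval 7.95 to 254; log2 fold change 4.42, and 6.82 without Ctrl replicate 2), and Col1a1, Col1a2, Col3a1 and Dcn had at most 9 counts over either group. Immune cell markers were higher in 4 of 5 tested (camera adjusted p = 0.0879), with the macrophage receptor gene Csf1r at 0.319 ± 0.0845 and 32.0 ± 2.73 CPM (6.59, SE 0.18) and Cd68 at 1.63 (SE 0.21). Smooth muscle markers were higher in 3 of 4 tested and lower in 1, among them Lmod1 (4.71, SE 0.42) and Mylk (0.96, adjusted p = 0.0219). The Mylk call ended without Ctrl replicate 3 (0.83, adjusted p = 0.0687), Ctrl replicate 4 (0.71, adjusted p = 0.0551) or YAP5SA replicate 2 (0.86, adjusted p = 0.0671). Of 2 endothelial markers tested, Egfl7 was higher (1.37) and Esam was at -1.03 and not called (adjusted p = 0.0523), or lower when adjusted over the list alone. Without Ctrl replicate 1 (-1.31, adjusted p = 0.0105) or YAP5SA replicate 1 (-1.35, adjusted p = 0.0300) Esam was called lower. Neural and glial markers were higher in 1 of 5 and lower in 3 (adjusted p = 0.556). Of the lower ones, Ano1 was at -0.32 (adjusted p = 0.0363), and its call ended with upper quartile scaling (-0.26, adjusted p = 0.0867) and with library size alone (-0.14, adjusted p = 0.350). It also ended without Ctrl replicate 1 (-0.22, adjusted p = 0.0825) or 3 (-0.33, adjusted p = 0.0512) and without YAP5SA replicate 1 (-0.30, adjusted p = 0.0797), 2 (-0.34, adjusted p = 0.0532) or 4 (-0.27, adjusted p = 0.0878). Lung and thyroid markers were higher in 4 of 5 and lower in 1 (adjusted p = 0.0944), with the surfactant protein gene Sftpd at 1.98 (SE 0.09) and the ciliogenesis factor Foxj1 at 3.40 (SE 0.19). Pancreas and liver markers were higher in 1 of 4 tested and lower in 3, and 0 erythroid markers were tested.

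**Figure D4:**
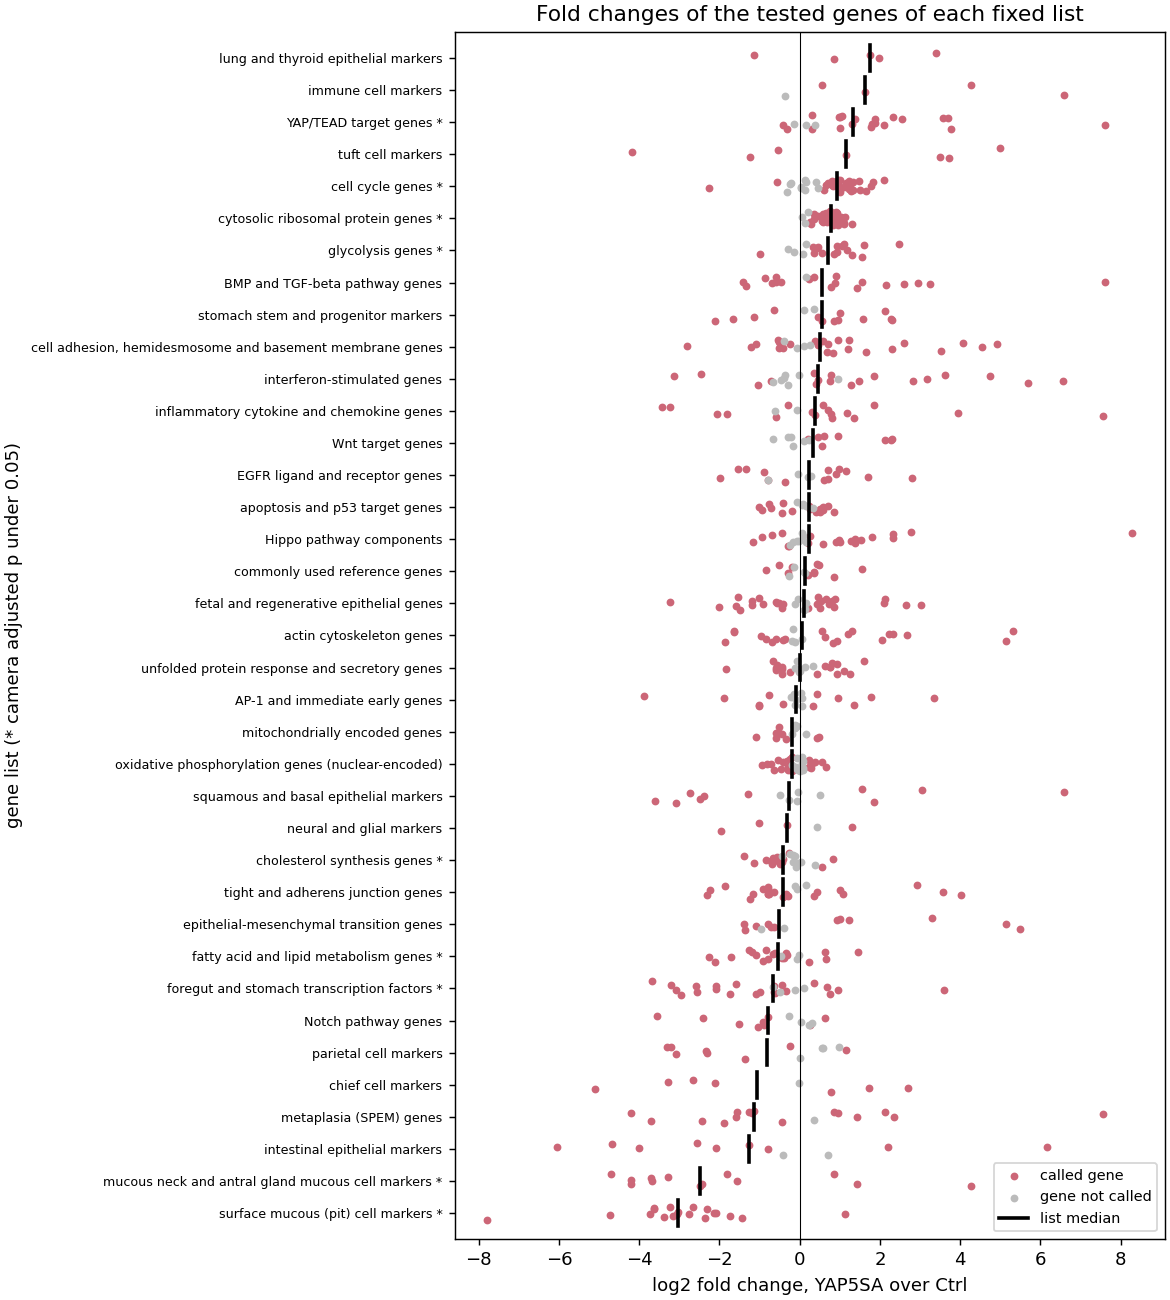
Log2 fold change (YAP5SA over Ctrl) of every tested gene in the 37 lists with at least 5 tested members, each point 1 gene, each bar the list median, ordered by median. Surface mucous (pit) cell markers lie lowest with a median of -3.02, and YAP/TEAD targets have a median of 1.34; medians of the fetal, AP-1, actin, unfolded protein and reference lists change sign with the scaling.

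Glycolysis genes were higher in 15 of 20, lower in 1 and not called in 4, with a median of 0.72 (camera adjusted p = 0.00592, and adjusted p = 0.65 with an estimated correlation). Pgk1 rose by 1.55 (SE 0.11), Eno1 by 1.10 (SE 0.08) and Pgam1 by 1.06 (SE 0.07). Fatty acid and lipid metabolism genes were lower in 15 of 22, higher in 4 and not called in 3, with a median of -0.53 (camera adjusted p = 0.014, and adjusted p = 0.41 with an estimated correlation). The oxidation enzyme gene Cpt1a was at -2.11 (SE 0.10), and the regulator Pparg at -1.70 (SE 0.14). Cholesterol synthesis genes were lower in 12 of 23, higher in 2 and not called in 9, with a median of -0.41 (camera adjusted p = 0.0304, and adjusted p = 0.65 with an estimated correlation). Without Ctrl replicate 3 this call ended (adjusted p = 0.0588, median -0.31). Ebp fell by 1.40 and Tm7sf2 fell by 1.13 on the log2 scale. Nuclear-encoded oxidative phosphorylation genes were lower in 19 of 38 and higher in 8 (adjusted p = 0.138), and mitochondrially encoded genes lower in 7 of 15, or 8 when adjusted over the list alone, and higher in 2 (adjusted p = 0.166). Mitochondrially encoded transcripts held 4.43% to 5.00% of counts in Ctrl and 5.03% to 5.75% in YAP5SA, led by mt-Co1 (0.44, SE 0.08).

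Interferon-stimulated genes were higher in 14 of 25, lower in 4 and not called in 7 (camera adjusted p = 0.137). Ifit2 rose by 6.57 (SE 0.32; 7.48 without Ctrl replicate 2) and Ifi44 by 5.70 (SE 0.40), while Oasl1 was at -3.14 and Mx1 at -2.45. Inflammatory cytokine and chemokine genes were higher in 11 of 19 and lower in 6 (adjusted p = 0.556), with the macrophage growth factor gene Csf1 at 3.94 (SE 0.22) and Il18 at -3.43 (SE 0.15). Unfolded protein response and secretory genes were higher in 10 of 26 and lower in 9 (adjusted p = 0.847), with the chaperone gene Hspa5 at 1.25 (SE 0.09), and their median of 0.005 was -0.007 with RLE scaling. Apoptosis and p53 target genes were higher in 11 of 23 and lower in 7 (adjusted p = 0.675), with Cdkn1a at -0.94. Commonly used reference genes were higher in 7 of 15 and lower in 4 (adjusted p = 0.556), with Pgk1 at 1.55, Gapdh at 0.86 and Actb at -0.84 and a median of 0.12 that was -0.03 when scaled on the list itself. Fry's test, which asks whether a list moves on balance one way without comparing it with other genes, called 30 of the 37 lists, and its mixed version, for change in either direction, called 37.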

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

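The tests below on the number of changed genes over the divisions of the libraries, on the size of the list medians, on sex-linked counts and on fibroblast, macrophage and mesothelial transcripts were chosen only after the result was seen.

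Each value of a named gene was compared with the other 3 libraries of its group by Dixon's ratio. This ratio is the gap to the nearest value divided by the range. Library totals, mitochondrial shares of counts and the shares of the 5 most counted genes were compared in the same way. Of 384 such groups 21 (5.47%) passed the critical ratio for 4 values at the 5% level, where chance alone passes about 1 in 20, and 7 of the 21 fell on YAP5SA replicate 4. In that library Ccn2 (ratio 0.8948, 1327 CPM against a mean of 1101 in the other 3), Cym (0.8918, 75.0 against 41.6), Efcab1 (0.9516, 0.684 against 0.166), Il33 (0.9028, 57.7 against 39.4) and Ndufa8 (0.8401, 51.4 against 47.6) were highest. Hbegf (0.8498, 269 against 362) and the Y-linked Kdm5d (0.9117, 47.3 against 76.6) were lowest there. In YAP5SA replicate 2 Ddc was highest (0.9215, 0.728 against 0.241), and Mki67 (0.8633, 29.9 against 38.0) and Tead1 (0.9819, 146 against 172) were lowest. In YAP5SA replicate 3 Pparg was highest (0.9007, 105 against 86.7) and Ifit2 lowest (0.9571, 15.5 against 20.6).

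In Ctrl replicate 1 Cym (0.9282, 2865 against 1338 CPM), Ly6a (0.8903, 585 against 422) and Siglecg (1.0, 0.0564 against 0) were highest. In Ctrl replicate 2 Tgfb2 (0.8881, 0.533 against 0.182) and Mfap5 (1.0, 0.118 against 0) were highest, and in Ctrl replicate 4 Camk2b (0.8507, 0.279 against 0.0139), Dlc1 (1.0, 0.168 against 0) and Ebp (0.9361, 103 against 93.2). Ctrl replicate 3 had the highest total (0.8975, 25841256 counts against a mean of 18537000). The ratios of Siglecg, Mfap5 and Dlc1 rest on 1 to 3 counts in a single library.

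The number of changed genes was set against chance by counting how many of the 35 divisions of the 8 libraries into 4 and 4 call as many. Only 1 of 35, the real one, did so for changed genes (8907, highest other 0), for higher genes (4577, highest other 0) and for lower genes (4330, highest other 0). So chance can be excluded only if the 8 samples are independent, which the labels do not say. Samples sharing a source within a group would give the same result. All other divisions mix the groups, so the group difference widens their spread, and 1 of 35 is the smallest share possible. Library size alone called 8943 genes, but this total tests little, because a shift in scaling trades lower calls for higher ones. It shifted the median of all genes from 0.02 to 0.19 and called 5742 higher and 3201 lower. Of the 8907 genes, 7778 (87.3%) stayed called, with no opposite sign, so for these scaling by a few abundant genes is argued against. Leaving out the genes above 1% of any library called 8899, but moved that median only to 0.01 and so tests little. Embryo sex cannot be told apart from genotype, since the Y-linked counts separate all 8 of 8 libraries along it, and genotype stays an open biological explanation, untested apart from sex.

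Vim, Cald1, Mmp14 and Csf1r rose in YAP5SA, and cells of another type in those cultures could be the source. Fibroblasts are argued against by Col1a1, Col1a2, Col3a1 and Dcn, whose summed CPM was 0.2088% of that of Vim, and macrophages by Ptprc, Tyrobp, Fcer1g, C1qa, C1qb and C1qc, at 0.28% of that of Csf1r. Other listed immune and mesenchyme markers did rise in counts per group from Ctrl to YAP5SA, among them Cd68 (955 to 3106), Itgam (5 to 53), Lyz2 (3 to 71) and Pdgfra (8 to 36). For mesothelial cells, Wt1, Gpm6a, Upk3b, Lrrn4 and Aldh1a2 summed to 436.3% of the CPM of Vim, but this sum is no measure of such cells, because most of it is Upk3b (107.6 ± 14.4 CPM without TMM scaling), which was also at 21.8 ± 9.90 CPM in Ctrl, where Vim was at 0.704. Mesothelial cells stay open because Aldh1a2 was at 0.573 CPM in Ctrl and 9.55 in YAP5SA and Wt1 at 0 and 1.14, and no value excludes them. All of these but Upk3b lay below Vim (27.2 CPM) in YAP5SA, with Gpm6a at 0.289 and Lrrn4 at 0.123.

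Cytosolic ribosomal protein genes rose with a median log2 fold change of 0.77. Bias with transcript length is argued against by other genes matched on length (GENCODE M21, GRCm38) and expression, whose median was -0.06165 over 10000 draws (central 95% of draws -0.41 to 0.19). Over 5 scalings the lowest median was 0.6209, while the median of all genes ranged from -0.13 to 0.19. Scaling differences of that size are thus argued against, but larger ones were not tried. All 5 scalings are relative, so a change in total RNA was not tested. The members move together between replicates of a group, with an estimated correlation of 0.847 after the group means are removed. With an estimated correlation the camera adjusted p was 0.65, but camera asks whether the list differs from other genes. Fry, which keeps the correlation between members and makes no such comparison, gave adjusted p = 0.000352 for a rise, and 37 of 40 genes were called. These values argue against joint variation of the size seen between replicates of a group. A source shared by all cultures of a group stays open. Genotype and sex are constant within each group, so the correlation of 0.847 says nothing on either, and they cannot be told apart here. Reads shared with pseudogenes were not tested.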

How the results depend on the processing

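The run without sex-linked genes was chosen only after the result was seen, as were the tests on list medians over the divisions. That run left out only Xist, Kdm5d, Uty, Ddx3y, Eif2s3y, Kdm5c, Kdm6a, Eif2s3x and Ddx3x, with 13803 genes still tested. It could therefore move the count of calls little, and it cannot separate sex from genotype. Against 8907 called genes (4577 higher, 4330 lower), DESeq2 called 9495, limma-voom 8949, RLE scaling 8911, upper quartile scaling 8870, library size alone 8943, no filter 9716, a filter at 1 CPM 8488, 1 surrogate variable 9388 and the run without sex-linked genes 8894. A minimum effect of 1 on the log2 scale left 2221 genes, 1185 higher and 1036 lower, as this test asks for a larger change by construction. Leaving out 1 library called 8299 to 8972 genes, 4212 to 4533 higher and 4087 to 4439 lower, and 8 to 11 lists. Camera called 9 lists, 14 with no low-count filter (the cause was not tested) and 1 with an estimated correlation. Fry, which does not compare a list with other genes, called 30. The estimated-correlation test also takes its degrees of freedom from the libraries rather than the genes, so its losses are not due to correlation alone. For the YAP/TEAD list the estimated correlation was -0.003, under the preset 0.01, yet the camera adjusted p was 0.0492 against 4.53e-06. Camera called 11 with limma-voom, which added the Hippo (adjusted p = 0.0359) and adhesion (0.0281) lists, and 11 with library size alone, which added the Hippo (0.0496) and intestinal (0.0490) lists. Without the filter the parietal (0.0102), Hippo and adhesion (both 0.0122), lung and thyroid (0.0210) and intestinal (0.0293) lists were added. No call took the opposite sign in any setting run. Among named genes Atp4a was also called with library size alone (adjusted p = 0.0492) and Ly6a likewise (adjusted p = 0.0239), and Esam with no filter (0.0311), the 1 CPM filter (0.0489) and 1 surrogate variable (0.0353), while Ano1 lost its call with upper quartile scaling (0.0867) and library size alone (0.350). The replicate numbers are not said to pair the groups, and the correlations of equal numbers, after removing the group means, were 0.065, 0.046, 0.090 and 0.281, best for their own number in 2 of 4 Ctrl libraries. The highest was that of the number 4 libraries, where Ctrl replicate 4 was at -0.10 to -0.16 with the other YAP5SA libraries. Both number 4 libraries also lay highest on the second principal component (26.8 in Ctrl and 23.0 in YAP5SA, next 11.5 in Ctrl replicate 1). A source shared by the number 4 libraries is thus not excluded. With the replicate block 9174 genes were called, 4715 higher and 4459 lower, and of the lists and the genes taken by the naming rule only Atp4a changed its call (0.61, adjusted p = 0.0357).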

Other observations

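The tests named here on the list medians, and the genes picked by their counts, were chosen only after the result was seen.

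Besides the Y-linked genes, several genes had 0 counts in all Ctrl libraries and at least 20 in each YAP5SA library. Grap, a signalling adaptor, had 76 to 110 counts, Pappa2, a protease that cleaves growth factor carriers, had 70 to 144, and Vgll1, a TEAD cofactor, had 33 to 46. Khdc1c had 23 to 30 and Pwwp4a 26 to 46. In all 11 genes met this rule in YAP5SA and 2, Gm42047 and Gm33302, met it in Ctrl.

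The fixed gene lists were also set against chance. At least 9 called lists, the real count, were found in 6 of 35 divisions of the libraries, with up to 12 in another division, so chance cannot be excluded for that count by this test. The other 5 all keep 3 libraries of a group together and so hold part of the group difference, and the 18 divisions with 2 libraries of each group called at most 5 lists. The mean size of the list medians, looked at after that count, was 0.710, and in only 1 of 35 divisions, the real one, was it as large (highest other 0.353). It reflects the same group difference as the gene counts and is no separate evidence.

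The 5 most counted genes held 9.51% to 10.4% of counts in the Ctrl libraries and 6.49% to 6.90% in the YAP5SA libraries.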
